A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

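Data of 4 arrays from 2 biological replicates were used. Each array compared total RNA of the drn1 deletion in BY4743 with that of wild-type BY4743, both from log-phase cultures in YPD kept at 30 °C, with RNA extracted by acid phenol, per the labels' protocols. RNA was labelled directly with the Ulysis kit in Alexa Fluor 532 (green) and Alexa Fluor 647 (red), per the labels' protocols. The deletion was in red on arrays 1 and 3 and in green on arrays 2 and 4, and arrays 1 and 2 formed replicate 1 and arrays 3 and 4 replicate 2. All 4 arrays were on 1 slide, so slides cannot separate the groups.

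The scans (scanner G2505B) were read with Feature Extraction 9.1.1.1 and protocol GE2-v5_95_Feb07, per the file headers. The mean intensity of each spot and the median intensity of its local background, with no correction, were taken as deposited, per the file headers. The deposited log ratio of the scanner software is a log10 ratio of red over green after background subtraction and dye normalization, per the file headers. The deposited series table holds a log2 ratio of red over green that was not turned for the dye swap. Its scale and direction were found from the values. The last 2 served only as alternatives, and the spots' median intensities only to find the scale of the series table. The 45220 spots of an array held 1417 controls, which were left out, and 39300 probes, of which 4503 had 2 spots. From 912 to 1080 spots per array were saturated in red and 0 to 1 in green.

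The files pair no probe with a gene name, and none has a position. No genome was used here, so no probe was given a gene name, DRN1, its neighbours and DBR1 were not checked, and none of the lists of genes fixed before the data were examined (snRNA, snoRNA, other structural RNA, rRNA, mitochondrial and mRNA lists) was applied by symbol. In their place, the layout was rebuilt from the probe sequences before any ratio was computed. Each 60-nt probe was reduced to the unit it repeats (median 21 nt), and units that overlap in the order of the probe numbers were joined into regions. A spliced junction found on both sides of a stretch that begins with GT and ends with AG in an unspliced window marked an intron. This gave 224 introns from 249 junctions, 174 with the usual GTATGT start and 196 with the branch motif TACTAAC, and 11 introns in tRNA-like regions. Exon probes lay within 60 nt of an intron. Regions were called tRNA-like by a B box (70 regions), box C/D-like by both boxes at their ends (14), ACA-end-like by an ACA near the end (7) or other (44). Their outer 100 nt on each side were taken as flanks. Regions tiled at a wider step and rich in A and T (34), tiled and spaced probes of a second numbering, and windows of 500 nt of the longest region made the other classes. These classes come from motifs alone. The planned step of genes was therefore run on such features.

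Intensities were background-corrected with normexp (offset 50) and loess-normalized within each array with limma 3.58.1 in R 4.3.3, with control spots at weight 0. Spots of a probe were averaged without outlier-flagged spots (0 to 4 per array). Ratios were turned to deletion over wild type, and the 2 arrays of a replicate were averaged, so that a dye effect cancels. A probe was tested where all its spots were well above background in wild type on all 4 arrays or in the deletion on all 4 arrays (11311 of 39300, 28.8%), and 11307 had a value in both replicates. limma fitted the mean of the 2 replicates against 0 with eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom the estimated prior degrees of freedom were infinite, so that all probes shared 1 standard error. The feature test used the median over a feature's tested probes on each array, and the intron test the difference of intron and exon medians on each array, averaged over the 2 arrays of a replicate. This departs from the plan, which averaged the 2 arrays before the median was taken. A median per array can fall on different probes in the 2 dye orientations, so part of the dye effect can stay. The departure was found after the results were seen, and the planned order was then run beside it. The tests on simulated data below used the order per array. Classes with at least 5 tested features were tested with camera, with a preset correlation of 0.01 and with an estimated one. A probe whose wild-type side was below background on all 4 arrays was given as at least N-fold, with the wild-type side raised to the lowest signal above background on each array.

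The rule for named features was fixed before the data were examined. It takes up to 15 features on each side with the largest changes among those past the threshold with the same sign on all 4 arrays, and up to 4 of each class with the same sign on all 4 arrays. The rule gave 7 features past the threshold. The single probes, the block of the long region, the spaced probes and the features whose arrays differed in sign were chosen after their values were seen. Identifiers are printed for 2 probes that rose and 2 that fell.

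The steps were tested on simulated data with the real dye effects and a standard deviation of 0.13 per array. The noise was normal and alike for all probes, with its size taken from a median-based spread of the difference between replicates. The ordinary standard deviation of that difference was 0.16, so the real data held more extreme values. The numbers of wrong calls below may therefore be too low for the real data. For the comparison of deletion and wild type over 11307 probes, 64 of 67 probes changed by 0.3 on the log2 scale were recovered, 67 of 67 at 0.5 and 66 of 66 at 1, with 6 wrong calls. Over 1144 features, 20 of 20 were recovered at each of the 3 sizes, with 14 wrong calls, 13 of them on features with 1 or 2 tested probes. Over 127 introns, 8 of 10 were recovered at 0.3 and 10 of 10 at 0.5 and at 1, with 2 wrong calls. A class shift of −0.1 passed camera with the preset correlation and not with an estimated one (adjusted p = 0.979).

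Alternatives changed the background correction, normalization, filter on dim probes, saturated probes, replicate structure, dye orientation, arrays and replicates used and the summary of features. Added after the data were seen were the planned order of averaging, a correction for the G content of the target RNA, since Ulysis labels G, a count of same signs only, the intron calls split by the side of the filter a probe passed by, features with at least 3 tested probes, and junction probes in place of exon probes. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.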

Results

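RNA abundance was compared between Saccharomyces cerevisiae cells lacking DRN1 and their wild type, the diploid strain BY4743, on 4 two-channel arrays. DRN1 encodes a homolog of Dbr1, the enzyme that opens intron lariats after splicing. Cells were grown in rich medium (YPD) at 30 °C to log phase, and total RNA was labelled directly, with no cDNA step. Each of 2 biological replicates was hybridised on 2 arrays with the dyes swapped, so every comparison below has n = 2. Each array carried 39300 probes, mostly short units repeated to fill 60 nt. They tile RNAs with their flanks, introns and spliced junctions, except 13794 spaced probes that form no tiled region. Of the spots that were not controls, 30.5% to 32.9% were well above background in the green channel and 30.6% to 37.3% in the red channel. The number of arrays limits the precision.

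The series asks which non-coding RNAs change when DRN1 is deleted. The transcript of DRN1 itself was not checked, because the files pair no probe with a gene name or a position, so the direction of every ratio rests on the labels alone. RNAs are described below by the class that the probe sequences give.

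Most probes differed little between the strains. Introns held 24 of the 65 higher calls, bodies of tRNA-like regions 13, the flank of 1 tiled region 8 and a short block of a long tiled region 7. Of 11307 tested probes, 65 were higher and 78 were lower in the deletion at an adjusted p under 0.05 (limma, two-sided). Of these, 42 and 31 had the same sign on all 4 arrays, as had 6.15% of all tested probes. Called probes were chosen for a large mean, which makes a same sign more likely, so this comparison is not a test. The dye effect has opposite signs on swapped arrays, so signs can differ where the replicates agree. The counts of higher and lower calls were 36 and 12 with no background subtraction, 44 and 16 with median centring, 25 and 11 with the scanner's log ratio and 57 and 16 with no filter on dim probes, and 97 and 124 with background subtraction floored at 0.5 and 78 and 104 with the series table's values. The mean log2 ratio of deletion over wild type was within 0.2 of 0 for 96.3% of the tested probes, and the smallest called change was 1.22-fold. The fit gave every probe the same standard error (0.08 on the log2 scale, n = 2), so the size of the mean decided each call and the agreement of the arrays is given beside it. Across the tested probes the values of the 2 replicates correlated with r = 0.26, and probes are not independent replicates.

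Under the main filter, introns held the most higher calls of any class. By share, the 5′ flanks of tiled regions with no box motif stood above them (8 of 162 tested probes, 4.94%). All 8 lay in 1 flank tiled with overlapping probes, so this share rests on 1 region and not on flanks as a class. Of 634 tested intron probes, 24 (3.79%) were called higher, against 41 of the 10673 other tested probes (0.384%; two-sided exact Fisher test, p = 2.75e-14, with neighbouring probes not independent). The count was 10 with both channels above background, 15 with the scanner's log ratio and 42 with no filter. Those 42 were among 2935 intron probes (1.43%), against 15 of 36357 other probes (0.0413%). In the 5′ flanks with no box motif, 3 of 792 probes (0.379%) were higher with no filter. With both channels above background, 10 of 605 intron probes were higher (1.65%) against 37 of 10216 others (0.362%; Fisher test, p = 0.000219). Under this filter the long region (14) and tRNA-like bodies (11 of 841, 1.31%) held more calls than introns. The 5′ flanks of tiled regions with no box motif again had a higher share (7 of 146, 4.79%). The other 14 intron calls were among 22 intron probes tested because only the deletion was above background on all 4 arrays, a filter that favours higher ratios, against 2 calls among 196 other such probes. The 24 probes lay in 18 of the 156 tested introns, which were 86 to 550 nt long, and 19 of them had the same sign on all 4 arrays. Of the 24, 17 were measured above background in wild type on at least 1 array. Their median log2 ratio was 0.42 (1.34-fold), with a range of 0.29 to 0.55. The other 7 were above background on all 4 arrays in the deletion and on 0 in wild type, with mean log2 signals of 7.72 to 8.56 in the deletion and 7.0 to 7.52 in wild type. These 7 were at least 1.19-fold to at least 2.07-fold higher. The adjusted p values of such probes belong to the fitted ratios, which use wild-type signals below background, and not to the bounds. The lowest bound was under the smallest called change (1.22-fold). The highest bound belonged to probe SH16584 (target CTGGGCGCTGAACACATG, in a 314-nt intron; adjusted p = 1.71e-43), whose deletion signal was 8.56 and whose wild-type signal was 7.36 on the log2 scale. The next was at least 1.68-fold higher, for target GTTCAAGAATAATATCAAGGGTTTTAAC at the 5′ end of a 447-nt intron (adjusted p = 2.68e-31, with mean log2 signals of 8.18 and 7.16). Introns of 314, 398 and 435 nt had 3 called probes each, of 9, 6 and 7 tested. Each of the other introns with a call had 1 called probe, of 1 to 9 tested, so most of these introns had a single call.

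**Figure D1:**
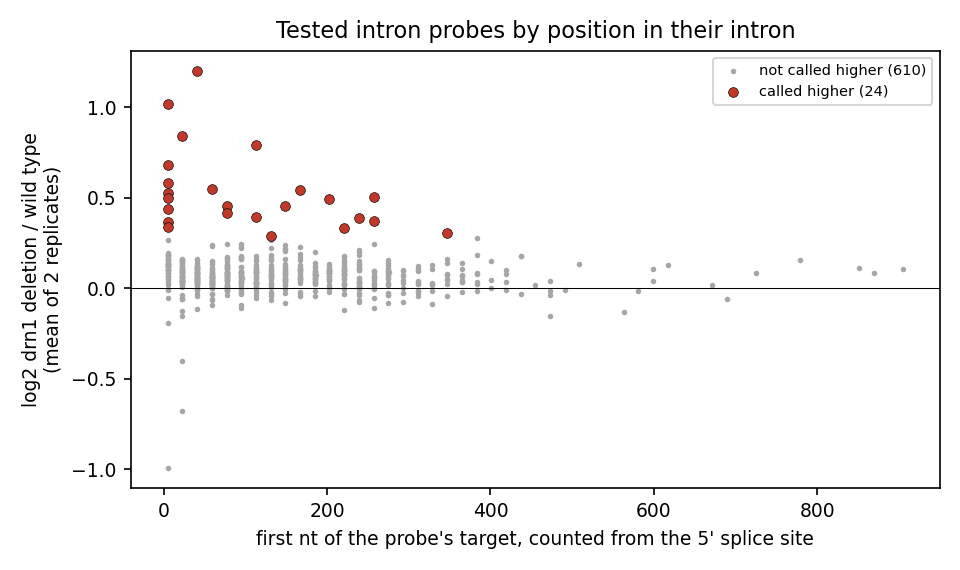
Each point is 1 of the 634 tested intron probes, with the first nucleotide of its target counted from the 5′ splice site on the x axis and its mean log2 ratio of deletion over wild type (n = 2) on the y axis. The 24 red points were called higher, and for 7 of them the wild type was below background on all 4 arrays, so that their fitted values are not bounds.

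The exons and spliced junctions of the same genes stood near 0. The exon and spliced-junction probes of 17 of the 18 introns had a median log2 ratio of −0.03, with a range of −0.06 to 0.07, and 4 of the 17 were above 0. At the level of whole introns, taken as the median of their tested probes on each array, 4 introns were higher and 3 lower. The intron of 86 nt was at least 1.36-fold higher (on 1 tested probe, with mean log2 signals of 7.92 and 7.08). Its adjusted p of 7.63e-25 (limma) belongs to the fitted log2 ratio of 0.84 and not to this bound. The intron of 133 nt rose by 0.55 on the log2 scale (1.47-fold; adjusted p = 1.27e-10, on 1 probe). Both had the same sign on all 4 arrays. The intron of 447 nt passed too (adjusted p = 1.81e-09), but only 1 of its 3 tested probes was called, which has only the bound above, the other 2 stood at 0.11 and 0.00, and its arrays split by dye. With the 2 arrays of a replicate averaged before the median over probes, the order that the plan had set, it stood at 0.11 and did not pass (adjusted p = 0.967). The fourth, of 398 nt (adjusted p = 0.000312), stood at 0.40 in replicate 1 and 0.31 in replicate 2 but had arrays of differing sign. It stood at 0.28 in the planned order (adjusted p = 0.0206). An intron of 83 nt fell by 0.40 on the log2 scale (adjusted p = 1.52e-05, on 1 probe), with the same sign on all 4 arrays. Introns of 111 nt (−0.68; adjusted p = 2.6e-16) and 213 nt (−0.46; adjusted p = 3.0e-07) also passed, at −1.38 and −0.92 in replicate 2 but at 0.02 and 0.00 in replicate 1.

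Intron RNA set against exon RNA of the same gene, the comparison nearest to the role of Dbr1, gave no shift that held in both replicates. Over 127 introns the median difference was 0.08 on the log2 scale and 97 were above 0, but the median was 0.16 in replicate 1 and −0.00 in replicate 2, and 52 introns were above 0 in both. Without array 1 the median was −0.04, and without array 2 it was 0.22. Leaving out 1 array keeps the dye effect in 1 replicate, so these values cannot decide whether the shift holds. limma called 3 introns higher and 3 lower relative to their exons (9 at an unadjusted p under 0.05), and 1 of the 6, the lower intron of 83 nt, had the same sign on all 4 arrays. Against the spliced junction, the median was 0.08 over 123 introns, and 3 passed. In the planned order, 1 intron was higher and 3 were lower relative to their exons, and 2 passed against the junction.

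The highest tested ratio lay in a block of neighbouring probes in a long tiled region of 7949 nt. This region held the stretch GTGCCAGCAGCCGCGGTAA, typical of small-subunit rRNA, from nt 1452, and is treated here as rRNA-precursor-like. In it, 7 neighbouring probes covering nt 6841 to 6888 (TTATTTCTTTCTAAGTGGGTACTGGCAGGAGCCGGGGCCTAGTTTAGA) had a mean log2 ratio of 1.28 (2.43-fold), with a range of 1.02 to 1.63 (2.03-fold to 3.09-fold). The block stood at 1.32 in replicate 1 and 1.24 in replicate 2, each of its probes had the same sign on all 4 arrays, and the largest of the 7 adjusted p values was 1.82e-31. The highest of all tested probes, SH11825 (1.63), was among them. The 24 other tested probes within 100 nt had a median of 0.05 and a range of −0.27 to 0.16. The mean log2 brightness of the block's probes was 8.90 to 12.96, against a median of 14.05 over the region. The region held 7 other probes called higher, of which 1 had the same sign on all 4 arrays, and 7 called lower, of which 0 had (limma; 827 of all tested probes had an unadjusted p under 0.05).

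**Figure D2:**
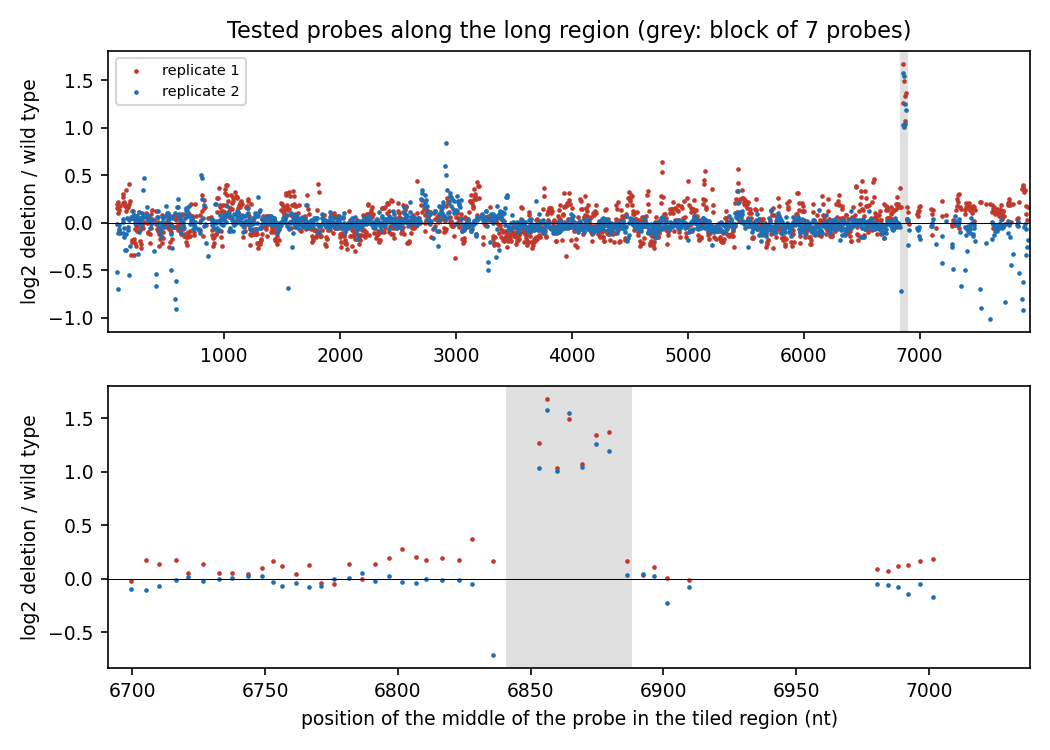
The log2 ratio of deletion over wild type is plotted for each tested probe against its position in the 7949-nt region, with replicate 1 in red and replicate 2 in blue. The upper panel shows the whole region and the lower panel the surroundings of the grey block of 7 probes, where both replicates were above 1.

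Among the other tiled RNAs, the 5′ flank of a 563-nt region rose by 0.33 on the log2 scale (1.26-fold; adjusted p = 0.00133, over 14 tested probes), and by 0.27 in the planned order (adjusted p = 0.0323). Its 4 arrays stood at 0.31, 0.29, 0.40 and 0.33, while the body of the same region stood at 0.05 (adjusted p = 0.980). Within this flank, 8 probes were called higher, 7 of them with the same sign on all 4 arrays, up to 0.53 for target TGTTTTACGTTTGAGGCCTCG. In the bodies of tRNA-like regions, which carry the internal promoter box of tRNA genes, 13 probes from 8 of the 70 regions were called higher (0.28 to 0.47), 6 of them with the same sign on all 4 arrays, and 0 of the 70 bodies passed as a whole (limma; 76 of all tested features had an unadjusted p under 0.05). As a class these bodies leaned the other way, with 50 of 70 below 0 and a median of −0.03. Of their probes on the array, 41.1% share a target with another probe, so the 13 need not be separate signals. With no filter on dim probes, 1 of 1186 probes in these bodies was called higher, and 3 of 792 in the 5′ flanks of tiled regions with no box motif. A 5′ flank of a 445-nt region with an ACA box near its 3′ end fell by 0.30 (adjusted p = 0.00964, on 1 probe), and the spliced junction of a 75-nt intron fell by 0.28 (adjusted p = 0.0193, on 1 probe). Both had the same sign on all 4 arrays. The other 2 features past the threshold, an AT-rich region of 270 nt (−0.30; adjusted p = 0.00739) and the 5′ exon beside a 114-nt intron (0.28; adjusted p = 0.0183, on 1 probe), did not. The AT-rich region stood at 0.04 in replicate 1 and −0.65 in replicate 2, whereas the exon stood at 0.30 and 0.26. The single probes of this exon and of the junction were not called in the probe test, where 0 of 211 tested 5′ exon probes and 0 of 537 junction probes passed.

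Spaced probes, which form no tiled region and have no class, gave 12 of the 31 lower calls with the same sign on all 4 arrays. Of 2617 tested spaced probes, these 12 were the only ones called lower. Their median log2 ratio was −0.42, and they were 1.22-fold to 1.72-fold lower. Probe JH4879 (TGGCGTATTGACTGAACA) stood at −0.78 and JH5783 (GACACTTTGGAACACGGC) at −0.67, and 2 pairs of the 12 were neighbours in the numbering. Another 3 spaced probes were called higher, and 0 of them had the same sign on all 4 arrays.

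Many of the lower calls rested on replicate 2. Of the 78 lower probes, 46 were within 0.2 of 0 in replicate 1 and below −0.4 in replicate 2. The medians of the 78 were −0.10 and −0.67. After a correction for the G content of the target, 47 probes were lower, 41 of them among the 78. The ratios of the 46 hardly moved (median of the mean −0.36 before and after), while their standard error rose from 0.08 to 0.10. The drop in calls therefore cannot be read as an effect of G content. With no background subtraction, median centring, the scanner's log ratio and no filter on dim probes, 12, 16, 11 and 16 probes were lower, and with floored subtraction and the series table's values 124 and 104. Tiled AT-rich regions held 27 of the 78, of which 7 had the same sign on all 4 arrays, and 17 lay in the bodies of tiled regions with no box motif, of which 5 had.

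**Figure D3:**
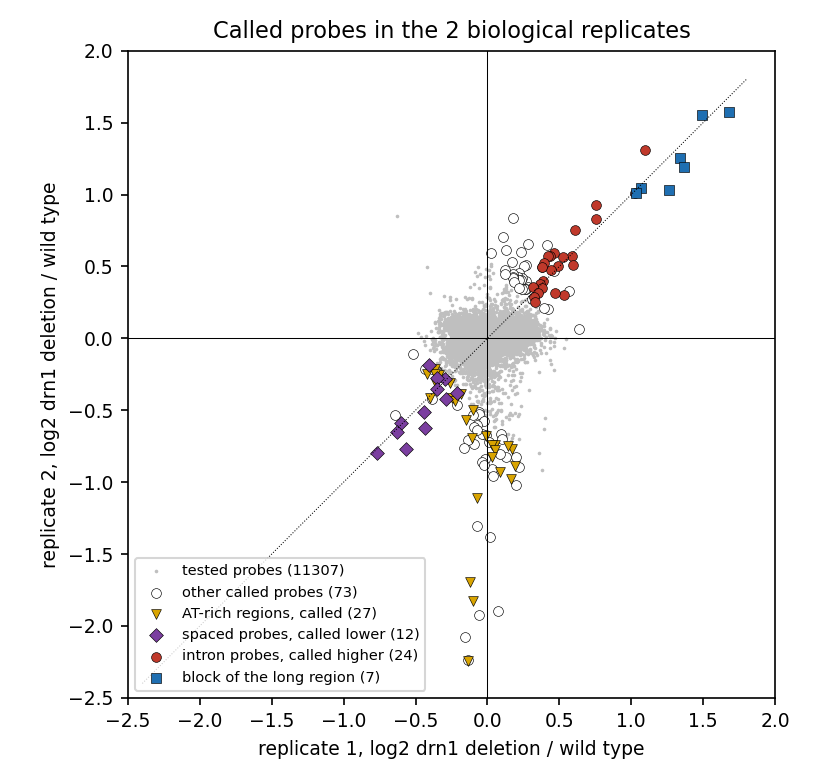
Each point is 1 probe, with its log2 ratio of deletion over wild type in replicate 1 on the x axis and in replicate 2 on the y axis, and the dotted line marks equal values. The 24 called intron probes, the 7 probes of the block and the 12 lower spaced probes lie near the line, while many other lower probes lie near 0 in replicate 1.

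Taken as whole classes, AT-rich tiled regions stood lower and introns higher by small amounts, and the calls held with a preset correlation only. Over 1144 tested features in 21 classes, 12 features passed, 6 higher and 6 lower, and 7 of the 12 rested on 1 tested probe. In the planned order of averaging, 11 of the 12 passed. The feature step made 14 wrong calls in simulated data, 13 of them on features with 1 or 2 tested probes, so calls on 1 probe are the least certain. The 12 do not exceed 14, but the simulated data also held planted changes. The 14 is thus not the number expected without any change, and it does not say how many of the 12 are wrong. With a preset correlation of 0.01, camera called 4 classes, and in the planned order also the bodies (−0.06; adjusted p = 0.0480) and 5′ flanks (0.08; adjusted p = 0.0477) of box C/D-like regions. AT-rich tiled regions had a median log2 ratio of −0.09 (28 of 31 below 0; adjusted p = 1.34e-10), introns 0.07 (138 of 156 above 0; adjusted p = 3.09e-07), tRNA-like bodies −0.03 (50 of 70 below 0; adjusted p = 0.00468) and probes across the 5′ splice site 0.06 (42 of 48 above 0; adjusted p = 0.00886). With an estimated correlation, 0 of the 4 passed (adjusted p = 0.821 for each). A shift of −0.1 planted in simulated data did not pass camera with an estimated correlation either (adjusted p = 0.979), so that setting cannot decide on shifts of this size. The AT-rich median was −0.02 in replicate 1 and −0.16 in replicate 2, and that of introns was 0.10 and 0.04. The 22 tested probes of 60 nt with no repeated unit had a median of 0.10 and spaced probes one of 0.05, so probes with no class shifted in the same direction as introns by a similar amount. The AT-rich median was −0.05 after a correction for the G content of the target, −0.04 with median centring and −0.02 with no filter on dim probes. The median of introns was 0.18 with median centring and 0.02 with no filter, and turned to −0.04 without array 1. The median of tRNA-like bodies turned to 0.04 when arrays were centred on their median with no loess, to 0.10 without array 2 and to 0.13 without array 4. Values with 1 array left out keep the dye effect in 1 replicate, so they cannot decide whether the shifts of introns and tRNA-like bodies hold. In the AT-rich class, regions of 356 nt (−0.21; adjusted p = 0.301) and 261 nt (−0.20; adjusted p = 0.301) had the same sign on all 4 arrays. The other 17 classes, with box C/D-like and ACA-end-like RNAs among them, had medians of −0.05 to 0.07.

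The ratios of single arrays followed the dyes. Turned to deletion over wild type, arrays with the same dye orientation correlated across probes with r = 0.91 and r = 0.93, and arrays with opposite orientations with r from −0.90 to −0.85. With any 1 array left out, limma called 0 probes (46 to 473 at an unadjusted p under 0.05), since the dye effect then stayed in 1 replicate.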

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

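The tests against brightness-matched probes, on the exons and junctions of the same genes, and all 3 tests on the probes lower in replicate 2 were chosen after the results were seen. Over 28 measures with 1 value per array, 2 had 1 array far from the other 3, and chance sets apart about 1 in 20. Array 1 had 1080 spots saturated in red, against 912 to 929 on the others. The 5′ flanks of ACA-end-like regions had a median log2 ratio of 0.0740 on array 1, against −0.10 to −0.08 on the others.

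Intron probes were called higher more often than other probes. A shift of dim probes is argued against by 10000 draws of probes outside introns matched in brightness, which held 3 higher calls at the median and 12 at most, against the 24 observed. The draws were not matched for the side of the filter a probe passed by. Of the 24, 14 passed by the deletion alone, so the filter may add to the count. The 10 others were 1.65% of 605 intron probes, against 0.362% of other probes. With no filter on dim probes, 42 of 2935 intron probes were higher (1.43%), against 15 of 36357 others (0.0413%). This argues against the filter alone as the source of the excess. After a correction for the G content of the stretch that a probe pairs with, 24 of the 24 were still called higher. The calls thus did not rest on a trend with this G content. Its correlation with red over green was weak (r from 0.01 to 0.10 over the arrays), so the correction could move little. More transcript of the same genes is argued against by the exon and junction median of −0.0256, where the called intron probes had 0.48 as fitted and 0.43 with 7 of them at their bound. What stays open is a biological one, that the deletion may leave more intron RNA of some genes. G in the rest of the labelled RNA, and pairing of these short probes with RNAs from elsewhere, were not tested and stay open too.

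The block of 7 probes in the long region held the highest tested ratio. Its mean log2 ratio was 1.28 both before and after the correction for G content, and 0 of its probes shared their target with another probe or were saturated. Shared or saturated probes are argued against, and so is a trend with the G content of the probes' targets, though the correction for it could move little. G in the rest of the labelled RNA was not tested. A higher level of this part of the RNA in the deletion may be biological, as a hypothesis found on these data; a variant in this stretch between the strains was not tested.

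Of the 78 lower probes, 46 were near 0 in replicate 1 and low in replicate 2. They were picked by those values, so the median of −0.10 in replicate 1 over the 78 cannot decide whether every deletion culture lost these RNAs, and 31 of the 78 had the same sign on all 4 arrays. After the correction for G content, the 46 kept a median of −0.753 in replicate 2, against −0.773 before. Their targets had a median G of 26.8%, near the 25% of all tested probes. The correction could therefore move them little and cannot decide on G content. Of the 46, 19 were still called, with a median mean log2 ratio of −0.36 before and after but a standard error that rose from 0.0833 to 0.103, because limma no longer gave every probe the same one. The targets of the 46 had a median G plus C of 52.6%, and those of the 11 most extreme (below −1 in replicate 2 and within 0.5 of 0 in replicate 1) of 61.1%, against 40.9% over all tested probes. The 11 had a median G of 47.4%, and their median in replicate 2 was −1.83 before the G correction and −1.76 after. A sequence-dependent effect in replicate 2 that this correction does not remove may therefore contribute. G content was not told apart from G plus C, and a difference between the cultures stays open.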

How the results depend on the processing

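The direction and the calls of the block of the long region held under each alternative except leaving out 1 array, where 0 of its 7 probes were called, and its mean stayed between 0.89 and 1.67. Of the 24 intron probes called higher, 24 were shared by background subtraction floored at 0.5, the series table's values, leaving out saturated probes, 4 independent arrays with a dye term and the G correction. No filter on dim probes shared 22, no background subtraction 21, median centring 20, the scanner's log ratio 15 and both channels above background 10. Aquantile changes the brightness of spots and not their log ratios, so its calls were the same by construction. The median of AT-rich regions stayed below 0, from −0.18 to −0.01, with −0.0546 after the G correction, −0.0409 with median centring and −0.0203 with no filter against −0.0925. The G correction left 3 of the 4 classes called and took the probe calls from 65 higher and 78 lower to 66 and 47. It also let the standard error differ between probes, so a lost call need not mean a changed ratio. Signal over background limited the tests to 28.8% of the probes. The causes below were not tested, except that one dye orientation, or leaving out 1 array, keeps the dye effect by construction, and that a stricter filter or a minimum of probes tests fewer.

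Of the 143 called probes, the count became 48 with no background subtraction, 221 with floored subtraction, 60 with median centring, 36 with the scanner's log ratio, 73 with no filter on dim probes and 73 with the same sign required. Arrays 1 and 3 alone gave 4156 calls and arrays 2 and 4 alone 4464. Leaving out 1 array gave 0, with 84, 46, 70 and 473 probes at an unadjusted p under 0.05 without arrays 1 to 4 in turn.

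The 12 called features became 4 with floored subtraction, 6 with median centring, 0 with the scanner's log ratio (68 at an unadjusted p under 0.05), 0 with no filter (90), 7 with both channels above background, 7 with at least 3 tested probes, 7 with the same sign required, 11 in the planned order of averaging, 328 and 409 with each dye orientation alone, and 0 with 1 array left out (13, 31, 6 and 165). The 4 called classes became 7 with floored subtraction, 6 in the planned order, 9 with arrays 1 and 3 alone, and 5 to 9 with 1 array left out.

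The intron minus exon median of 0.08 became 0.27 with arrays 1 and 3 alone and −0.12 with arrays 2 and 4 alone, and ranged from −0.0354 to 0.216 with 1 array or 1 replicate left out, at −0.0354 without array 1 and −0.00368 without replicate 1. The 24 higher intron probes became 15 with the scanner's log ratio, 42 with no filter, 10 with both channels above background, 261 with arrays 1 and 3, 49 with arrays 2 and 4, and 0 with 1 array left out (14, 17, 17 and 64 at an unadjusted p under 0.05).

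The median of introns was 0.179 with median centring and 0.0171 with no filter, turned to −0.10 with arrays 2 and 4 alone and ranged from −0.0432 to 0.182 with 1 array or replicate left out, lowest without array 1. That of tRNA-like bodies turned to 0.0437 with median centring and 0.27 with arrays 1 and 3 alone, was −0.315 with arrays 2 and 4 alone, and ranged from −0.18 to 0.13, at 0.10 without array 2 and 0.13 without array 4. With 1 biological replicate there are no residual degrees of freedom, so counts have no value there. The fit with replicate as a random block could not be had, since a correlation was estimated for 0 of 11307 probes. The transcript of DRN1 had no value under any setting.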

Other observations

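The tests of border probes and of 5′ ends were chosen after the results were seen, and that of the part after the branch motif before. Called intron probes gathered at the 5′ ends of introns. Of 49 tested probes that start within 10 nt of the 5′ splice site, 8 were called higher (16.3%), against 16 of 585 other tested intron probes (2.74%; two-sided exact Fisher test, p = 0.000204). This comparison was not split by the side of the filter a probe passed by. Of the 24 called intron probes, 14 passed by the deletion alone, so the filter may add to it. RNA of the 5′ ends of some introns may therefore be more abundant in the deletion, a hypothesis from these data that needs other arrays.

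Among the called probes, 8 formed 4 groups that share a target, all higher, and their log2 ratios differed within a group by at most 0.04. In the target TCTGGGAGCTGCGATTGG, in the 5′ flank of the 563-nt region and in a region of the second numbering, the ratios were 0.44 and 0.46.

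Whether spliced-out introns are kept, as the loss of a Dbr1 homolog might leave them, was not decided. Over 60 introns, probes across an exon-intron border differed from intron probes by −0.0129 on the log2 scale at the median (−0.03 in replicate 1 and 0.01 in replicate 2). The border probes of the 9 called introns that had one had a median of 0.06, against 0.53 for the called probes of the same introns, but those were selected for being high. For the part after the branch motif, which a lariat keeps as its tail, 19 probes were tested and 0 were higher (limma), against 24 of 568 before it (4.23%), and 19 are too few to tell the tail from the rest.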
